A study of Macaca mulatta with 6 samples.

How the data were processed

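Bisulfite sequencing measures DNA methylation by converting unmethylated cytosines, so that methylated and unmethylated cytosines at CpG sites (a cytosine followed by a guanine) can be told apart in the reads. Per the labels, DNA came from peripheral blood mononuclear cells (lymphocytes and monocytes, purified on a Ficoll gradient) of 6 adult female rhesus macaques. The labels place 3 animals at rank 1, the high-ranking group, and 3 at rank 5, the low-ranking group. The submitters' processing notes name Bismark, a bisulfite read aligner and methylation caller, without a version. The genome build and any filter on sites are not given in the sources used here. The listed positions may therefore be a selection of the CpGs in the genome.

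The authors deposited a single headerless table in BED layout for the whole series. Its first 3 columns hold a chromosome name and the start and end of one cytosine. They are followed by 12 further columns that carry no names. Nothing in the labels or the table ties any of these 12 columns to an animal or to a rank group, and matching them by their order or values would be a guess. The 12 unnamed columns were therefore not used. For columns without names the plan foresaw a description of each column's values without a comparison, and this was not made either. No methylation level and no sequencing depth per animal is reported, and none of the tests planned before the data were examined was run. These were the tests of genome-wide level, CpG density class, annotation class, chromosome, tile, promoter, gene body, single CpG, gene list, similarity and spread of the animals, and enrichment. The rule for naming genes and tiles rested on those tests, so it named none. The gene lists fixed in advance (T cell, B cell, NK and cytotoxic cell, monocyte and dendritic cell, granulocyte, erythroid and platelet, inflammation, glucocorticoid, interferon, DNA methylation machinery, stress and behaviour, imprinted, germline and housekeeping genes) gave no result. A genome or annotation in the coordinates of the table was not used here, so no position was assigned to a gene, exon, intron or promoter.

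What was analysed is the catalogue of CpG positions, which belongs to no single animal. The table was split at any white space, since it has spaces in place of some tabs. The spaces numbered 2591385 over 26958235 lines, a number equal to 9.61% of the lines. Start and end differed by 1 base on every line, positions increased along each chromosome, and 0 listed positions were adjacent bases, so each CpG appears once and not once per strand. Coordinates are given 1-based. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

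Each chromosome was cut into 1 kb tiles from the tile of its first to that of its last listed CpG. The tiles were classed by their number of CpGs as 1 to 4, 5 to 9, 10 to 19, 20 to 39, and 40 or more, limits set before the data were examined. Tiles of the last class are called dense. Density was computed per kb of the span from the first to the last listed CpG and, separately, per tile with a listed CpG. A run of CpGs was defined as at least 40 consecutive CpGs, each at most 50 bases from the one before. Spacing is the number of bases from one listed CpG to the next. The count at each spacing was divided by the median count of up to 8 spacings on either side, of which fewer lie below where the spacing is under 10 bases, and a ratio above 1.3 was called over-represented. All choices other than the limits of the tile classes, and all results reported here, were chosen after the table had been opened. The density, tile and run computations, and the count of spacings that recur in a fixed order, were tested on simulated positions. All 4 planted values were recovered. The ratios of a spacing to its neighbours were not tested this way. The catalogue is a full count of what the table lists, so its counts have no replicate or sampling error. The relation between density and chromosome span was tested with density counted in each of the 2 ways, with Pearson's r and Spearman's rho and 100000 random permutations each, two-sided. The first of these was repeated on 3 other sets of chromosomes.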

Results

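The series profiled DNA methylation in peripheral blood mononuclear cells of 6 adult female rhesus macaques (Macaca mulatta), 3 of high social rank (rank 1) and 3 of low rank (rank 5). The design asks whether DNA methylation in circulating immune cells differs with social rank. That comparison was not made here, because the 12 columns of values carry no names and could not be tied to animals or rank groups. The results below describe the CpG positions that the table lists, and none of them compares animals. How many of these positions were covered by reads in any animal is not given here.

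The table listed 26958235 CpG positions on 20 autosomes, the X chromosome and a sequence named chrUr. The autosomes held 25805743 of them, or 95.7%, the X chromosome held 1143203, and chrUr held 9289 over 0.441 Mb. Chromosome 1 had the most positions, 2290432 between bases 142 and 228252164. Chromosome 18 had the fewest of the autosomes, 685680.

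CpG positions were spread unevenly between chromosomes. Across all autosomes there were 9.52 listed CpGs per kb of span. Chromosome 19 was the densest, at 14.6 per kb, followed by chromosome 16 at 13.9, chromosome 10 at 12.9 and chromosome 20 at 11.1. Chromosome 5 was the sparsest autosome, at 7.52 per kb, so that the autosomes differed by up to 1.94-fold. The X chromosome, of which female cells carry an active and an inactive copy, had 7.43 listed CpGs per kb, 0.780 times the autosomal density. Counted per tile with a listed CpG, the X chromosome had 8.002 CpGs and lay above chromosome 5, at 7.78, while chromosome 19 reached 18.7.

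**Figure D1:**
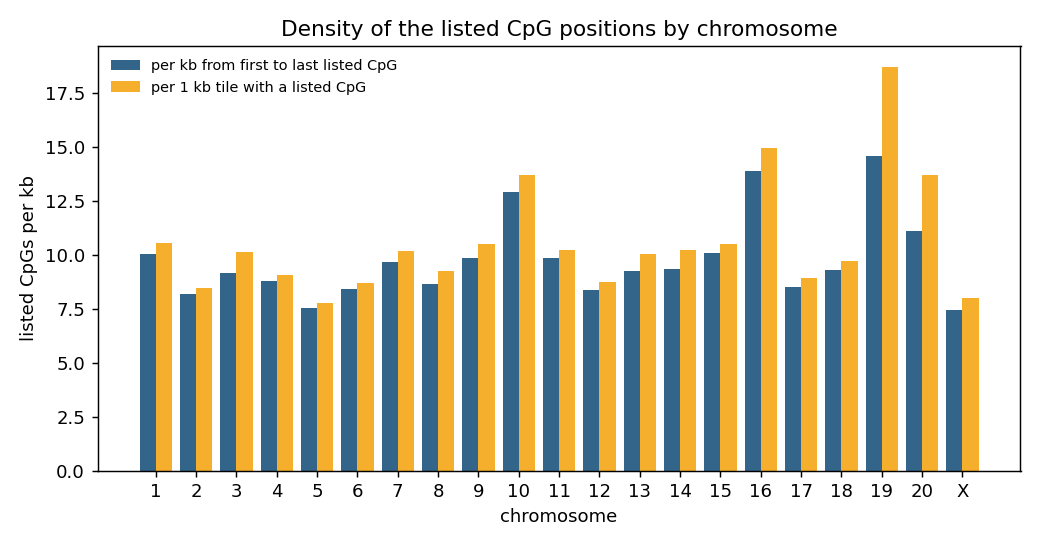
Listed CpGs per kb (vertical axis) for each autosome and the X chromosome (horizontal axis), counted over the span from the first to the last listed CpG (blue bars) and per 1 kb tile with a listed CpG (yellow bars). Chromosome 19 is highest by both counts, at 14.6 and 18.7, and the X chromosome is lowest by span only, at 7.43.

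CpG density tended to be higher on shorter autosomes, with clear exceptions. Chromosome 18, at 73.6 Mb, had 9.32 listed CpGs per kb, and chromosomes 17 and 12 had 8.54 and 8.40, all below the 9.52 of the autosomes together, while chromosome 1, the longest at 228 Mb, had 10.03. Across the 20 autosomes, density and span were negatively correlated, with Pearson's r = -0.58 (permutation p = 0.0063) and Spearman's rho = -0.51 (permutation p = 0.0216). With density counted per tile with a listed CpG, r was -0.58 (permutation p = 0.0048) and rho was -0.47 (permutation p = 0.0360). The Benjamini-Hochberg adjusted values over these 2 relations were 0.0063 for both r and 0.0360 for both rho. Without chromosomes 1 and 19, the autosomes farthest from the median span, r was -0.60. Without chromosome 19 alone, r was -0.49 (permutation p = 0.0310) and rho was -0.43 (permutation p = 0.0661). These are correlations across chromosomes of one genome, which are not independent replicates. The densest autosomes, 19, 16, 10 and 20, were all short, at 64.4, 78.8, 94.9 and 88.2 Mb. No correlation was computed without all of them, so whether density falls with span among the other autosomes was not tested.

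Most tiles with a listed CpG held fewer than 10 listed CpGs. Tiles with 10 or more held a larger share of the positions than of the tiles, as any class above the mean number per tile must. Tiles with 1 to 4 CpGs made up 25.2% of the tiles with a listed CpG and held 7.30% of the positions. Tiles with 5 to 9 CpGs made up 37.7% and held 25.4%, and those with 10 to 19 made up 26.6% and held 35.4%. Tiles with 20 to 39 CpGs made up 9.07% and held 23.0%. The 39548 dense tiles, with 40 or more CpGs, made up 1.47% of the tiles and held 8.91% of the positions. Such CpG-dense stretches, known as CpG islands when they also meet criteria on base composition, are in mammals often found at gene starts and are there mostly unmethylated.

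The frequency of dense tiles had a wider range across autosomes than CpG density, which differed by up to 1.94-fold. The 2 ranges are not alike, since one is of a count past a limit and the other of a mean. Chromosome 19 had 56.0 dense tiles per 1000 tiles and chromosome 16 had 32.7, against 14.2 over all autosomes and 6.04 on chromosome 5. The range across autosomes was 9.28-fold, set by chromosomes 19 and 5. Dense tiles held 21.6% of the CpGs of chromosome 19 and 5.10% of those of chromosome 5. The X chromosome had 6.97 dense tiles per 1000, 0.491 times the autosomal value, and these held 5.76% of its CpGs against 9.04% on the autosomes. On the X chromosome 33.4% of the tiles with a listed CpG held 1 to 4 CpGs, against 24.7% on the autosomes. The densest tile was on chromosome 1, from base 4306001 to 4307000, with 168 CpGs. The next was on chromosome 5, from base 2741001 to 2742000, with 165.

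Runs of closely spaced CpGs numbered 19888, had a median length of 741 bases and a median of 67 CpGs, and held 5.79% of the listed positions. There were 23.8 runs per Mb on chromosome 19, 15.7 on chromosome 16, 3.40 on chromosome 5 and 3.96 on the X chromosome, against 7.10 over all autosomes. The largest run, on chromosome 15 from base 107030943 to 107036189, held 576 CpGs in 5247 bases. The next, on chromosome 19 from base 1232604 to 1238185, held 570 CpGs in 5582 bases. The third lay on chromosome 15 from base 1410888 to 1414752 and held 452. These regions are given in the coordinates of the table, whose genome build is not given in the sources used here, and were not assigned to genes.

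Some stretches of the chromosomes held no listed CpG at all, and whether they hold sequenced bases is not given in the sources used here. In 154 places, neighbouring listed CpGs were at least 100000 bases apart, and these intervals added up to 77.3 Mb. The longest stretch without a listed CpG was 10.2 Mb on chromosome 20, from base 34254549 to 44407539. Chromosome 19 had one of 8.46 Mb, from base 23905248 to 32364256, chromosome 13 one of 5.38 Mb, from base 90365732 to 95741387, and the X chromosome one of 3.55 Mb, from base 57641215 to 61194377. Tiles without a listed CpG made up 22.2% of the span of chromosome 19 and 19.1% of that of chromosome 20, against 7.20% on the X chromosome and 3.40% on chromosome 5.

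Neighbouring CpGs were a median of 41 bases apart. The median was 24 bases on chromosome 19, 58 on chromosome 5 and 55 on the X chromosome. Spacings of 10 bases or less made up 19.6% of all spacings, and spacings above 1000 bases made up 0.415%. Among the 98 spacings from 2 to 99 bases, 6 were over-represented against the spacings beside them. The spacing of 8 bases occurred 765281 times, 1.73 times the median of its neighbours, and that of 4 bases occurred 845496 times, 1.70 times its neighbours. The spacings of 24, 38, 20 and 32 bases exceeded their neighbours 1.46, 1.45, 1.33 and 1.305 times. Fewer spacings exist below the shortest ones, and with as many neighbours below as above the ratios of 8 and 4 bases were 1.61 and 1.57. Counted that way, the same number of spacings, 6, passed the limit outside dense tiles, with 8 bases at 1.84 and 4 bases at 1.73 times their neighbours. Inside dense tiles, also counted that way, only the spacing of 38 bases passed, at 1.301. Those of 4, 8, 20, 24 and 32 bases were there at 0.986, 1.01, 1.15, 1.24 and 0.977 times their neighbours. The spacing of 2 bases has no shorter neighbour and could not be judged with as many neighbours below as above. With the first count, 5 spacings passed inside dense tiles. These were 2, 3, 4, 6 and 38 bases, at 1.68, 1.57, 1.45, 1.46 and 1.301 times their neighbours.

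**Figure D2:**
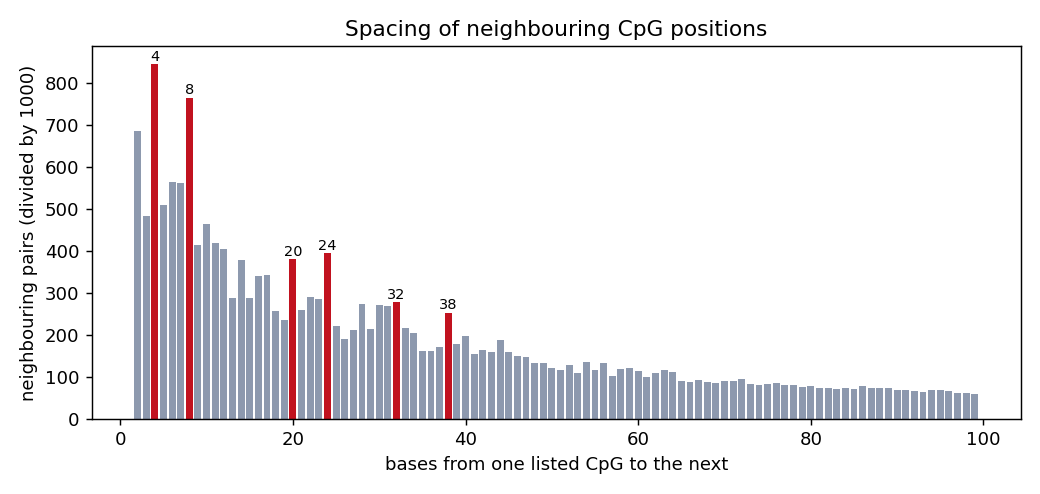
Number of neighbouring pairs of listed CpGs divided by 1000 (vertical axis), at each spacing from 2 to 99 bases (horizontal axis), over all chromosomes. Red bars with numbers mark the 6 spacings more than 1.3 times as frequent as the median of up to 8 spacings on either side, which were 4, 8, 20, 24, 32 and 38 bases, and grey bars are all other spacings.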

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

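All results and alternatives here were chosen after seeing the data. The alternatives planned for the methylation comparisons were not run, since those comparisons need columns tied to animals. The planned description of each unnamed column's values, which needs no such tie, was not made either. The planned tests did not pair the animals and no column could be tied to an animal, so no paired analysis was made. The share of CpGs in dense tiles was 8.91% and depended on the tile size: 13.4% in 500 base tiles with 20 or more CpGs and 3.24% in 5 kb tiles with 200 or more. Shifting the 1 kb tiles by 500 bases gave 8.90%. Dense tiles were less frequent on the X chromosome than on the autosomes in every setting run, with a ratio of 0.491 that moved to 0.567 in 500 base tiles and 0.384 in 5 kb tiles. The CpG density of the X chromosome was 7.43 per kb of span and 8.002 per tile with a listed CpG. The second count leaves out the tiles without a listed CpG, 7.20% of those on the X chromosome. The cause of the shifts of the dense-tile values with tile size was not tested. The correlation of density with span stayed negative in all 4 alternatives, with r from -0.60 to -0.49 and a permutation p under the threshold for r in each. Spearman's rho without chromosome 19 had a permutation p of 0.0661. None of the alternatives left out chromosomes 10, 16 or 20, which are also dense and short. Whether the relation holds without them was not tested.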

Other observations

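The tests on the X chromosome were chosen after the density of each chromosome had been seen, and the comparison of recurring runs with the most frequent run of each shuffled order was chosen after the runs had been seen. The test of spacings outside dense tiles was fixed before its result was seen. Its outcome was nonetheless largely set in advance. The spacing of 24 bases was already over-represented over all listed positions, of which dense tiles held only 8.91%.

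Some runs of spacings between CpGs recurred in a fixed order. The most frequent run of 5 consecutive spacings was 4, 5, 38, 2 and 4 bases, found 14979 times. The second was 4, 2, 38, 5 and 4 bases, found 14851 times, which is the same run read backwards. When the order of spacings was shuffled within each chromosome 10 times, these runs occurred 1 and 2 times in total. The most frequent run made only of over-represented spacings was 24, 20, 4, 8 and 4 bases, found 8409 times in the listed order, 8349 times read backwards, and 1 time in total over the 10 shuffled orders. The spacings of 2 and 5 bases in the first 2 runs did not pass the limit over all listed positions, at 1.28 and 1.06 times their neighbours. With as many neighbours below as above, that of 5 bases was at 0.817, and that of 2 bases could not be judged. The run that starts with 24 occurred 6.63 times per Mb on chromosome 19, 5.40 on chromosome 16, 2.14 on chromosome 5 and 2.22 on the X chromosome. Chromosome 8 had the lowest rate, 2.07. These rates are per Mb of span and were not adjusted for CpG density, which was also highest of the autosomes on chromosomes 19 and 16.

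One hypothesis is that these runs may be copies of one CpG-rich repeated sequence. The 8409 occurrences are consistent with that, since the most frequent run of such spacings in any of the 10 shuffled orders occurred 5 times. The shuffling excludes only an independent order of spacings, so other sources of a recurring order stay open. The run and its reverse held 4.24% of the 395308 pairs at a spacing of 24 bases. That number equals 13.4% of the 125445 pairs above the median of the neighbouring spacings. Only exact matches of all 5 spacings were counted, so copies with a changed spacing and other runs with 24 are missed. The cause of most of the excess at 24 bases stays open. The excess at 24 bases was not restricted to dense clusters of CpGs, since that spacing exceeded its neighbours 1.446 times outside dense tiles and 1.24 times inside them. No sequence was used here, so whether any repeat is involved was not tested directly.

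The X chromosome had 0.780 times as many listed CpGs per kb as the autosomes together. Stretches without a listed CpG did not account for this, since the ratio was 0.789 when only tiles with a listed CpG were counted, although the X chromosome then lay above chromosome 5. Fewer dense tiles on X did not account for it as the whole cause either, since the ratio was 0.802 with dense tiles left out. No biological explanation was tested.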
